A study of Mus musculus with 9 samples.

How the data were processed

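RNA from 9 libraries of sorted mouse lung cells was sequenced, with 3 libraries per group and 3 to 4 mice pooled per library. Per the labels, the sorted cells were more than 98% pure and the RNA integrity number was above 6.3, and the tumour cells or saline were injected in 200 µl. Per the submitters' processing notes, reads were aligned to GRCm38 with TopHat2 2.1.0, counted per gene with HTSeq and normalized with DESeq2 1.10.0. The deposited signal values are counts per gene that the authors divided by a size factor for each library and rounded to 2 decimals. Dividing each column by its smallest step gave whole reads for 100% of the values up to 2000 reads, within 0.05 read, and the reads so recovered set the depth per library. The signal per read ran from 0.316 to 2.61. Whether molecular identifiers were counted is not stated, so intervals and floors cover counting error only.

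The deposited table held 54670 entries. Of these, 63 whose gene name had been turned into a date were left out (0.219% of the total), as were 116 exact duplicates and 42 with the name and values of another entry. A further 215 shared a name or identifier (0.289% of the total). Of the 54449 genes left, 99.9% matched a gene of GENCODE M21, from which positions, GC content and transcript length were taken. Genes with a mean value of at least 5 over all 9 libraries were tested, which left 13642.

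The groups were compared with limma 3.58.1 in R 4.3.3, on log2(value + 1) in 1 fit of all 9 libraries with a variance trend, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. All tests were two-sided. The p-values of single genes measure the spread between pools of mice. Those of gene lists come from a comparison of members with the other genes. At a preset correlation between members they do not measure how a list varies between pools. The comparisons were Siglec-F high against naive, Siglec-F int against naive and Siglec-F high against Siglec-F int, as labelled. The comparisons, tests, gene lists, other settings and rule for naming genes were fixed before the data were examined, except where stated. Gene lists (29 of pathways and 14 of cell types) were tested with limma's camera at a preset correlation of 0.01, where at least 5 members were tested, and again with an estimated correlation. Their p-values were adjusted over the lists of each comparison. A list of pigment cell markers and a list of mesenchymal and matrix genes were chosen after seeing the data. Both have 25 genes, and the fixed lists also hold 2 of the former and 6 of the latter. Since their genes were picked for the levels seen, they are described by counts and medians and no p-value is given for them. The rule for naming genes took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 50 in the higher group and no overlap between the groups. From each list it took up to 3 called members per direction with the smallest adjusted p, or otherwise the members with the highest mean, and it added a fixed set of eosinophil, interferon and cytokine genes. Of that set, 1 gene is not reported here. For a gene with 1 to 3 reads in a group, the read ratio is given with its counting interval. The overlap of both comparisons with naive was set against 100 simulations. In these all 9 libraries were redrawn without a difference between groups, and both comparisons shared the simulated naive libraries.

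The results were recomputed with other pseudocounts, filters, scalings and variance priors, and a fit of only the groups compared. They also included the replicate number as a block, the removal of each library in turn, a fold minimum of 2, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Added after seeing the data were the removal of both Siglec-F high library 1 and Siglec-F int library 2, the removal of the trend with GC content and length (span 0.3), and equal totals without the mitochondrial genes. edgeR called 3550, 2875 and 0 genes in the 3 comparisons, and DESeq2 called 4964, 4018 and 6.

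The procedure was tested on simulated data with 201 changed genes in each of 5 runs. limma recovered 71.0% of 16-fold and 21.8% of 4-fold changes between Siglec-F high and naive, and 3.69% of its calls were false. Between Siglec-F int and naive it recovered 74.0% and 19.4%, and 6.51% of its calls were false. Between Siglec-F high and int, camera recovered 96% of lists with every member raised 1.5-fold. Those lists were random and their genes were drawn independently of each other. The preset correlation was thus not tested on members that vary together. Pairs of libraries within a group were checked for having been drawn from the same molecules, and their chi-square per degree of freedom ran from 17.0 to 151, so that none was a repeat of another. Shares of reads carry 95% Wilson intervals from scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.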

Results

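RNA was sequenced from 9 libraries that the labels describe as lung eosinophils, granulocytes of type 2 immunity, sorted from C57BL/6 mice. The libraries labelled naive (n = 3) came from mice injected with saline alone. The others came from mice given PyMT tumour cells through the tail vein, and their labels divide the sorted cells by surface Siglec-F. These form a high group (n = 3) and an intermediate group, called int (n = 3). Each library pooled 3 to 4 mice, so n counts pools. The libraries labelled naive held 4453385, 2205949 and 5529406 reads, those labelled Siglec-F high 4941900, 7171066 and 5148291, and those labelled Siglec-F int 7517513, 11566723 and 12495639. Between 15002 and 20052 genes per library had a value above 0. Values are deposited normalized counts, given as mean ± SD over n = 3 libraries per group. Fold changes are on the log2(value + 1) scale, ± SE, with limma's adjusted p, and this scale understates the change of genes with low values.

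Siglecf, Ccr3 and Epx, which help define eosinophils, were scarce in every library, while other members of the eosinophil identity list, such as Ear2, were not. Siglecf, the gene of the sort marker (ENSMUSG00000039013.16; chromosome 7, 43351341 to 43359531, GRCm38), stood at 12.6, 31.3 and 4.18 normalized counts in the libraries labelled naive, 17.6, 3.58 and 14.5 in those labelled Siglec-F high and 6.98, 20.2 and 11.1 in those labelled Siglec-F int. These values rested on 28, 39 and 96 reads per group. The log2 fold changes of Siglecf were -0.26 ± 0.87 between high and naive (adjusted p = 0.834), -0.05 ± 0.87 between int and naive (adjusted p = 0.973) and -0.21 ± 0.87 between high and int (adjusted p = 0.954). Their signs rested on single libraries, since without high library 2 the first and last were 0.37 and 0.42, and without naive library 2 or 3 the second was 0.60 or -0.72. Ccr3, the eotaxin receptor (chromosome 9, 124021972 to 124031689), had 0 reads in the libraries labelled naive and 29 and 33 reads in the libraries labelled Siglec-F high and int, where it stood at 24.1, 0 and 5.97 and at 0, 3.37 and 7.91. Epx, eosinophil peroxidase (chromosome 11, 87864000 to 87875536), had 3, 20 and 16 reads in the naive, high and int groups, all from naive library 1, Siglec-F high library 3 and Siglec-F int library 3, without which each group is at 0. Prg2, which encodes the major basic protein of the granules, reached 379.5 in Siglec-F high library 3 and 106 in Siglec-F int library 3, and 15.0 or less in each remaining library. Ear2, a ribonuclease of eosinophils that alveolar macrophages also express, stood at 309 ± 163, 409 ± 145 and 170.2 ± 85.5 in the naive, high and int groups. Ptprc, the pan-leukocyte antigen CD45, stood at 207 ± 168, 908 ± 303 and 1500.3 ± 745.

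Genes of pigment cells were abundant in the libraries labelled naive. Pmel, the premelanosome protein (ENSMUSG00000025359.10; chromosome 10, 128704195 to 128720238), stood at 15399 ± 4593 in the libraries labelled naive, 40.8 ± 30.7 in those labelled Siglec-F high and 64.0 ± 4.08 in those labelled Siglec-F int. Dct, an enzyme of melanin synthesis (chromosome 14, 118012790 to 118052244), stood at 22839 ± 4342, 186 ± 193 and 157 ± 74.5, and Sox10, a neural crest transcription factor (chromosome 15, 79154908 to 79165240), at 10401 ± 2159, 19.4 ± 16.2 and 51.1 ± 11.4. A list of pigment cell markers, chosen after the values were seen, took 1.75% of the reads in naive library 1 (95% Wilson interval 1.74 to 1.77), 1.52% in library 2 (1.50 to 1.53) and 2.01% in library 3 (1.99 to 2.02). Its share in the libraries from tumour-injected mice ran from 0.0202% (0.0190 to 0.0215) in Siglec-F high library 1 to 0.0500% (0.0487 to 0.0512) in Siglec-F int library 3. Relative to the libraries labelled naive, 20 of its 22 tested members fell in those labelled Siglec-F high, with a median of -6.39. In those labelled Siglec-F int 20 fell, with a median of -6.57. Between high and int its median was -0.15. These levels go against the cell type in the labels, so every direction reported here is drawn between libraries as they are labelled.

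**Figure D1:**
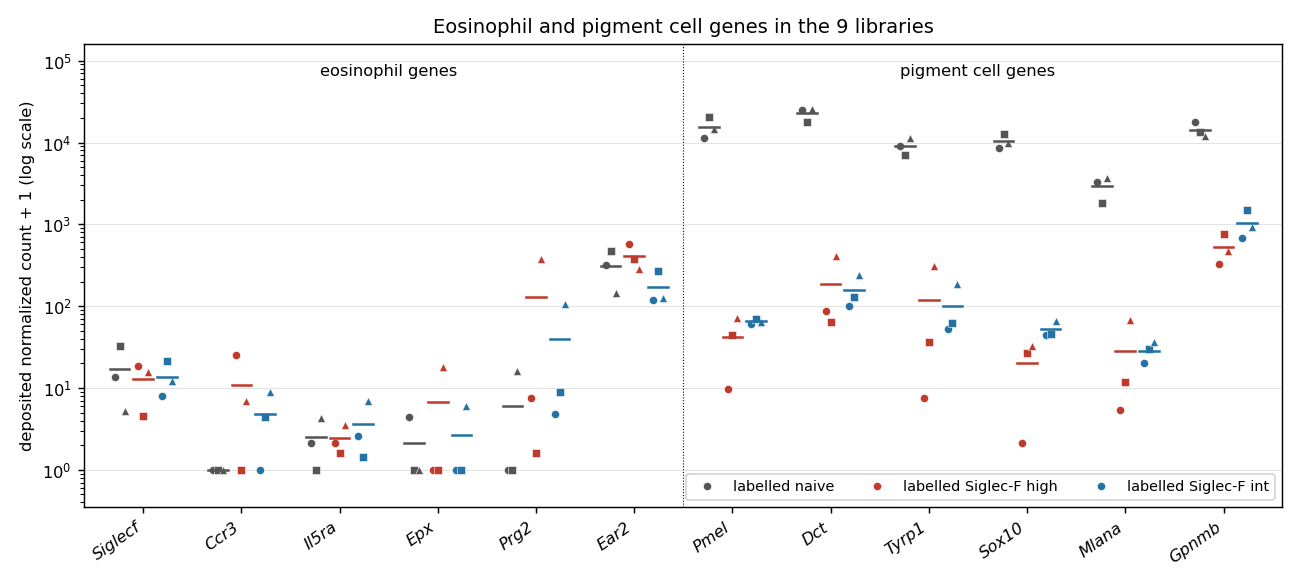
Deposited normalized counts + 1 (log axis) of eosinophil genes (left) and pigment cell genes (right), where each point is a library, its shape the replicate number, its colour the group as labelled, and each line a group mean (n = 3). Siglecf lay between 3.58 and 31.3 in all 9 libraries, and Pmel averaged 15399 in the libraries labelled naive and 40.8 and 64.0 in those labelled Siglec-F high and int.

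The first comparison asked which genes differ in the Siglec-F high cells of lungs reached by tumour cells. Relative to the libraries labelled naive, those labelled Siglec-F high held more transcripts of several secreted proteins. Inhba, a subunit of activin A (ENSMUSG00000041324.14; chromosome 13, 16011851 to 16031621), rose to 1613 ± 264 normalized counts, a log2 fold change of 6.30 ± 0.42 (adjusted p = 7.68e-05). Ccl2, a chemokine that attracts monocytes (chromosome 11, 82035571 to 82037453), rose from 1639 ± 578 to 35898 ± 12228, by 4.46 ± 0.36 (adjusted p = 9.88e-05). The alarmin Il33 (chromosome 19, 29925114 to 29960718) and its receptor Il1rl1 (chromosome 1, 40429570 to 40465415) rose by 5.46 ± 0.52 and 5.79 ± 0.52 (adjusted p = 0.000219 and 0.000162). The largest falls were those of pigment cell genes, with Sox10 at -9.71 ± 0.83 (adjusted p = 0.000137) and Pmel at -8.90 ± 0.60 (adjusted p = 7.68e-05). Other large falls were those of Ptgds, prostaglandin D synthase, at -8.61 ± 0.99 and of Mc1r, the melanocortin receptor, at -7.97 ± 0.76. Among the largest rises was Scx, a transcription factor of tendon cells, with a read ratio of 162 and a counting interval of 55.1 to 786, since the libraries labelled naive held 3 of its reads. Prrx1, a transcription factor of limb and connective tissue mesenchyme, rose by 6.58 ± 0.92 (adjusted p = 0.000978).

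Lists of inflammatory genes were higher in the libraries labelled Siglec-F high than in those labelled naive. Of 30 IFN-gamma response genes 16 rose, 0 fell and 14 were not called, and 17 rose and 1 fell when adjusted over the list alone (median 1.87, camera adjusted p = 1.71e-06, adjusted p = 0.243 with an estimated correlation). Those that rose included Gbp7, a guanylate-binding protein, at 2.97 ± 0.32, Casp1, the protease of the inflammasome, at 3.16 ± 0.43, and the chemokine Cxcl10, from 233 ± 146 to 1889 ± 1144. Cd274, which encodes PD-L1, was at 0.57 ± 0.42 (adjusted p = 0.306). Of 32 TNF and NF-kB targets 16 rose and 16 were not called, and 16 rose and 2 fell when adjusted over the list alone (median 1.19, camera adjusted p = 9.19e-05, adjusted p = 0.365 with an estimated correlation). They included Tnfaip3 and Nfkbia, inhibitors of NF-kB, at 3.29 ± 0.34 and 2.02 ± 0.30, and Ptgs2, the inducible cyclooxygenase (chromosome 1, 150100031 to 150108227), at 4.21 ± 0.62, while Tnf itself was at 0.34 ± 0.56 (adjusted p = 0.660). Tnf was at 0.96 without high library 1, -0.04 without high library 2, 0.09 without high library 3 and 0.13 without naive library 1. It was called only with both high library 1 and int library 2 left out (adjusted p = 0.0430, the lowest over its alternatives). Of 25 chemokines 12 rose, or 12 with 1 falling when adjusted over the list alone (median 1.29, camera adjusted p = 0.000882, adjusted p = 0.199 with an estimated correlation). Among 24 cytokines and growth factors 11 rose, as many as when adjusted over the list alone (median 1.08, camera adjusted p = 0.000262, adjusted p = 0.199 with an estimated correlation). Besides Il33, they included Lif, a cytokine of the interleukin-6 family, at 3.68 ± 0.38 and Areg, a ligand of the EGF receptor, at 5.14 ± 0.70. Ccl5, a chemokine for T cells, was at -1.23 ± 0.81 (adjusted p = 0.258), but at -0.11 without high library 1 and -1.85 without high library 2. Its values in high libraries 1, 2 and 3 were 6.58, 84.7 and 69.9. Immediate early genes, which also respond to tissue dissociation, rose in 16 of 31 members, as many as when adjusted over the list alone (median 1.05, camera adjusted p = 8.47e-06, adjusted p = 0.199 with an estimated correlation), with Egr1 at 2.87 ± 0.31 and Zfp36 at 2.22 ± 0.27.

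Genes of energy metabolism were lower in the libraries labelled Siglec-F high than in those labelled naive. Of 28 glycolysis and hypoxia genes 16 fell, 2 rose and 10 were not called, and 17 fell and 4 rose when adjusted over the list alone (median -1.80, camera adjusted p = 6.33e-05, adjusted p = 0.199 with an estimated correlation). Car9, a hypoxia-induced carbonic anhydrase (chromosome 4, 43506966 to 43513729), stood at 2120.1 ± 51.3 in the libraries labelled naive and 203 ± 15.4 in those labelled Siglec-F high (-3.38 ± 0.26, adjusted p = 9.79e-05), and Pgk1, phosphoglycerate kinase (chromosome X, 106187100 to 106203699), at 20244 ± 2969 and 3649 ± 520.5 (-2.47 ± 0.25, adjusted p = 0.000281). Gapdh, a common reference gene of this list named after its values were seen, stood at 12755 ± 2196 and 1602 ± 974 (-3.25 ± 0.49, adjusted p = 0.00149). Of 38 nuclear genes of oxidative phosphorylation 26 fell and 12 were not called, and 29 fell when adjusted over the list alone (median -1.34, camera adjusted p = 1.11e-08, adjusted p = 0.322 with an estimated correlation), among them Uqcrq and Sdhb, subunits of respiratory complexes, at -2.35 ± 0.28 and -3.17 ± 0.42. The 13 protein genes of the mitochondrial genome had a median of 0.20 and were not called as a list (camera adjusted p = 0.634). That median was -0.25 without high library 1, -0.09 without naive library 3 and between 0.33 and 0.53 without each other high or naive library, so its sign was not settled. The list was called lower after removal of the GC and length trend (adjusted p = 0.00154, range over its alternatives 0.00154 to 0.858). Ribosomal protein genes fell as a list (median -0.70, 14 of 54 called and 13 when adjusted over the list alone, camera adjusted p = 0.000773, adjusted p = 0.687 with an estimated correlation). That call ended when the trend with GC content and length was removed (adjusted p = 0.946, range over its alternatives 1.99e-06 to 0.946).

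Markers of other cells moved with these lists. Of 16 markers of monocytes and interstitial macrophages 8 rose, as many as when adjusted over the list alone (median 1.45, camera adjusted p = 0.000322, adjusted p = 0.479 with an estimated correlation), among them F13a1, a coagulation factor subunit, from 55.9 ± 21.7 to 647 ± 255, and Fn1, the fibronectin that fibroblasts also make (chromosome 1, 71585520 to 71653200), from 965 ± 65.8 to 10474 ± 1698. Of 14 markers of fibroblasts and smooth muscle 7 rose, as many as when adjusted over the list alone (median 1.21, camera adjusted p = 0.00134, adjusted p = 0.400 with an estimated correlation), with the matrix gene Dcn at 4.63 ± 0.49 and the growth factor receptor Pdgfra at 3.10 ± 0.41. A list of mesenchymal and matrix genes, chosen after the values were seen, rose in 20 of 25 members (median 2.78). The eosinophil identity list was also called higher (median 1.06, 4 of 14 tested members over all genes and 4 when adjusted over the list alone, camera adjusted p = 0.0486, adjusted p = 0.497 with an estimated correlation). Its called members were Il1rl1, Itgam and Csf2ra, receptors that other myeloid or lymphoid cells also carry, and Adgre1, the F4/80 antigen of macrophages. The calls of Itgam and Csf2ra were lost without naive library 1, 2 or 3 or without Siglec-F high library 1, with ranges of 0.00176 to 0.0674 and 0.00399 to 0.0938 over their alternatives. The call of the list was lost without naive library 1 (adjusted p = 0.0713), naive library 3 (0.153, median 0.70) or Siglec-F high library 3 (0.113, median 0.63). It was also lost with TMM scaling (0.0522) and with a pseudocount of 0.5 (0.0505), over a range of 0.00625 to 0.153. The 5 tested eosinophil granule genes had a median of 0.87 and were not called as a list (camera adjusted p = 0.406). Their median was 0.28 without naive library 3, 0.52 without high library 3 and 1.46 without naive library 2.

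In all, limma called 4266 of 13642 genes (31.3%) between the libraries labelled Siglec-F high and naive, 1999 higher and 2267 lower, and 17 of 42 lists, 13 higher and 4 lower. None of the lists was called with an estimated correlation, where the smallest adjusted p was 0.199. edgeR on the recovered reads called 3550 genes (2172 higher, 1378 lower), and 3267 genes were called in the same direction by both tools. Rescaling to equal totals gave 2141 higher and 1611 lower genes, and doing so without the mitochondrial genes gave 2326 and 1702. Equal totals moved the median log2 fold change of all genes from -0.11 to 0.02, TMM factors to 0.04 and quantile normalization to 0.01. The list tests compare members with the other genes and so are relative to it. Without naive library 1 the count was 2770, and the lower genes numbered 1355, 1336 and 1341 without naive libraries 1, 2 and 3.

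The second comparison asked the same of the cells with intermediate Siglec-F. Relative to the libraries labelled naive, Inhba rose in those labelled Siglec-F int to 1528 ± 515 (6.17 ± 0.42, adjusted p = 0.000106) and Ccl2 to 25284 ± 5765 (3.98 ± 0.36, adjusted p = 0.000212). Il1rl1 rose by 5.12 ± 0.52 (adjusted p = 0.000415). Crabp1, which binds retinoic acid in the cytoplasm, rose from 19.7 ± 16.9 to 1063 ± 604 (adjusted p = 0.00507). Ifi206, an interferon-induced gene, had a read ratio of 305 with a counting interval of 54.6 to 12049, since the libraries labelled naive held 1 of its reads. Pmel was at -7.85 ± 0.60 (adjusted p = 0.000119), and Trpm1, an ion channel of melanocytes and retina, at -7.67 ± 1.04 (adjusted p = 0.00114).

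Interferon genes were higher in the libraries labelled Siglec-F int than in those labelled naive. Of 34 type I interferon response genes 22 rose and 12 were not called, and 28 rose when adjusted over the list alone (median 2.26, camera adjusted p = 4.16e-10, adjusted p = 0.215 with an estimated correlation). They included the antiviral genes Ifit1, from 88.6 ± 68.5 to 532 ± 219.9, and Mx1, at 5.37 ± 1.05. Of 30 IFN-gamma response genes 18 rose and 12 were not called, and 22 rose when adjusted over the list alone (median 2.18, camera adjusted p = 8.02e-11, adjusted p = 0.0850 with an estimated correlation). Cxcl9 and Cxcl10 (chromosome 5, 92346638 to 92348889), chemokines that draw T cells, rose by 4.60 ± 1.04 and 3.08 ± 0.48, and Gbp7 by 3.73 ± 0.32. Cd274 rose by 1.80 ± 0.42 (adjusted p = 0.0129), a call lost without Siglec-F int library 2 or 3 (range over its alternatives 0.000148 to 0.0572). Of 25 pattern recognition and inflammasome genes 14 rose, or 17 when adjusted over the list alone (median 2.27, camera adjusted p = 1.90e-07, adjusted p = 0.236 with an estimated correlation), with Ifi204, a sensor of DNA, at 5.02 ± 0.51 and Clec7a, the receptor of fungal glucans, at 2.87 ± 0.48. TNF and NF-kB targets rose in 18 of 32 members, or 26 with 1 falling when adjusted over the list alone (median 1.51, camera adjusted p = 6.78e-09, adjusted p = 0.127 with an estimated correlation), and Tnf was at 1.51 ± 0.56 (adjusted p = 0.0745). Tnf was called under 9 alternatives, among them without high library 1 (adjusted p = 0.0145), with a range of 0.00473 to 0.237. Of 15 genes of MHC class II antigen presentation 3 rose, as many as when adjusted over the list alone (median 1.81, camera adjusted p = 0.000400, adjusted p = 0.338 with an estimated correlation). Without int library 2 the median was 1.16. They included Ctss, a protease of the endosome, at 2.84 ± 0.52, and the costimulatory ligand Cd86 at 5.09 ± 1.05, while H2-Ab1, a class II chain, was at 1.65 ± 0.69 (adjusted p = 0.111), and at 1.00 without int library 2, with a range of 0.0101 to 0.336 over its alternatives.

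Beside these lists, 10 of 16 markers of monocytes and interstitial macrophages rose, or 14 when adjusted over the list alone (median 2.47, camera adjusted p = 2.23e-08, adjusted p = 0.215 with an estimated correlation), with the monocyte chemokine receptor Ccr2 at 3.78 ± 0.53 and F13a1 at 3.55 ± 0.43. Fibroblast and smooth muscle markers were not called as a list (median 0.58, camera adjusted p = 0.0858), although 4 of 14 rose and 1 fell, or 5 and 1 when adjusted over the list alone. Their median was 0.38 without int library 1 and 0.84 without int library 2, where the list was called higher (adjusted p = 0.00897), as it was after removal of the GC and length trend (0.00502), over a range of 0.00502 to 0.141. The mesenchymal and matrix list rose in 15 of 25 members (median 2.47). The list of cytokine receptors and JAK-STAT signalling rose in 10 of 27 members, or 11 when adjusted over the list alone (median 1.19, camera adjusted p = 5.22e-05, adjusted p = 0.236 with an estimated correlation). Among them were Csf2ra, a chain of the GM-CSF receptor, at 2.21 ± 0.38, and Ifngr1, a chain of the IFN-gamma receptor, at 2.04 ± 0.33. The called members also include Il1rl1, the receptor of Il33, so not all belong to the JAK-STAT pathway. Oxidative phosphorylation fell in 30 of 38 genes, or 33 when adjusted over the list alone (median -1.44, camera adjusted p = 1.28e-15, adjusted p = 0.114 with an estimated correlation), with the cytochrome oxidase subunit Ndufa4 at -3.19 ± 0.34. Glycolysis and hypoxia genes fell in 17 of 28 members and 1 rose, or 18 and 3 when adjusted over the list alone (median -1.38, camera adjusted p = 5.08e-06, adjusted p = 0.0651 with an estimated correlation), with Car9 at -3.52 ± 0.26 and Pgk1 at -2.87 ± 0.25. The eosinophil identity list was called higher (median 1.11, 6 of 14 tested members over all genes and 6 when adjusted over the list alone, camera adjusted p = 0.0494, adjusted p = 0.338 with an estimated correlation). Its called members were Il1rl1, Itgam, Adgre1 and the cytokine receptor chains Csf2ra, Csf2rb and Csf2rb2, which other myeloid cells also carry. That list was not called without naive library 1 (0.0546), naive library 3 (0.132), int library 2 (0.0982) or int library 3 (0.0595, median 0.68). The call was also lost with equal totals (0.0583, or 0.0556 without the mitochondrial genes), TMM scaling (0.0615) and a pseudocount of 0.5 (0.0511). So was it with only the groups compared (0.0514) and without both Siglec-F high library 1 and int library 2 (0.0724), over a range of 0.00749 to 0.132. Among 24 surface and activation genes of inflammatory and tissue eosinophils 9 rose and 2 fell, as many as when adjusted over the list alone (median 1.20, camera adjusted p = 0.00274, adjusted p = 0.338 with an estimated correlation). They included Fcgr2b, an inhibitory Fc receptor of many myeloid and B cells, at 2.88 ± 0.45, and Cd69, an early activation marker of leukocytes, at 4.28 ± 0.76. The eosinophil granule genes were not called as a list (median -0.15, camera adjusted p = 0.770), and Prg2 was at 2.72 ± 1.94 (adjusted p = 0.338), or 1.38 without int library 3. The median of the granule genes was 0.03 without int library 1, -0.47 without int library 2, -0.49 without int library 3, -0.29 without naive library 2 and -0.65 without naive library 3, so its sign was not settled.

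**Figure D2:**
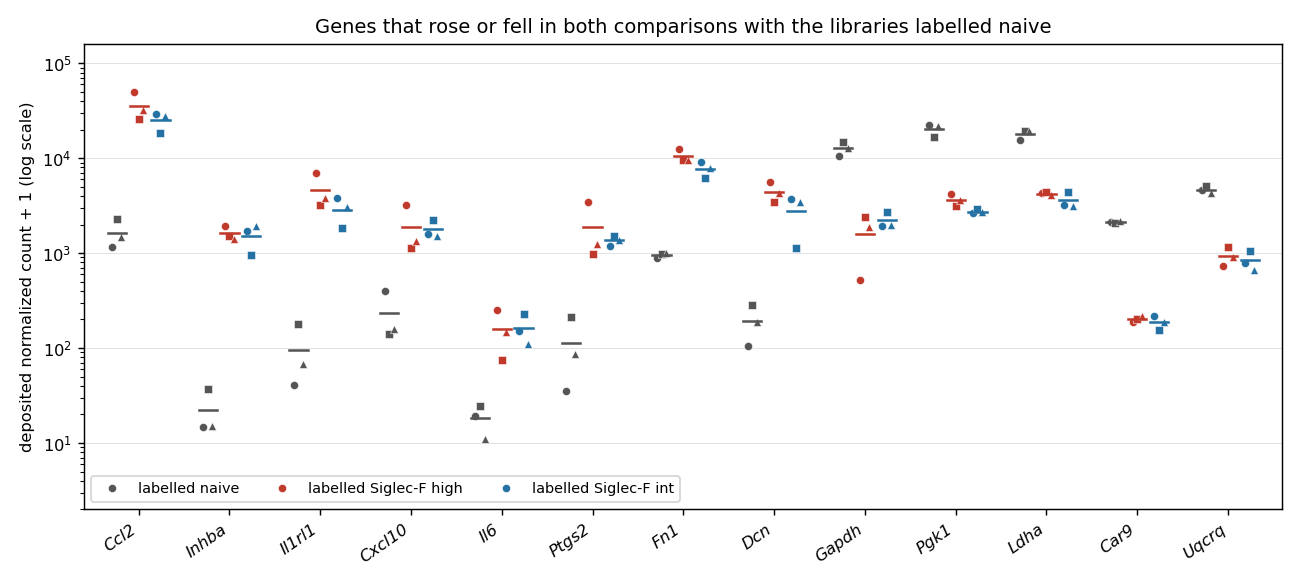
Deposited normalized counts + 1 (log axis) of genes that rose or fell in both comparisons with the libraries labelled naive, where each point is a library, its shape the replicate number, its colour the group as labelled, and each line a group mean (n = 3). Ccl2 averaged 1639 in the libraries labelled naive, 35898 in those labelled Siglec-F high and 25284 in those labelled Siglec-F int, and Car9 2120.1, 203 and 186.

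Between the libraries labelled Siglec-F int and naive, limma called 3036 of 13642 genes (22.3%), 1634 higher and 1402 lower, and 23 of 42 lists, 19 higher and 4 lower. None of the lists was called with an estimated correlation, where the smallest adjusted p was 0.0651. edgeR called 2875 genes (1837 higher, 1038 lower), of which 2568 were called in the same direction by limma. Equal totals gave 2009 higher and 898 lower genes, and 2013 and 1011 without the mitochondrial genes. They moved the median log2 fold change of all genes from -0.02 to 0.23, and TMM factors moved it to 0.14. These calls depended on single libraries. The count was 1497 without Siglec-F int library 1, 1401 without int library 3 and 1939 without naive library 1. It was 5167 without Siglec-F high library 1, which entered through the shared estimate of spread. The higher genes numbered 816 and 751 without int libraries 1 and 3, and the lower genes 681 and 650 without these, 2760 without high library 1, and 846, 922 and 826 without naive libraries 1, 2 and 3.

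The calls of both comparisons overlapped in 2547 genes, 1374 higher and 1173 lower in both, with 0 called in opposite directions. Genes high in both included Inhba, Ccl2, Il1rl1, Fn1 and Ptgs2, and genes low in both included Pmel, Sox10, Car9, Pgk1 and Uqcrq. Independent calls would share 239 higher and 233 lower genes. Across genes, which are not independent replicates, the fold changes of both comparisons had a Pearson r of 0.894 and a covariance of 2.74. Groups simulated 100 times without any change, with all libraries redrawn, gave r = 0.501, a covariance of 0.280 and 0 shared calls. The observed covariance exceeded the simulated value by 2.46. With no difference simulated, such values follow from the shared group alone, so they do not test for a common response of high and int. The simulations also held no pigment cell difference between naive and the other libraries. Part of the excess may come from the shared naive libraries, which were too few to be divided between the comparisons. The overlap was 1349 and 1275 genes without Siglec-F int libraries 1 and 3, and 1625 without naive library 1.

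**Figure D3:**
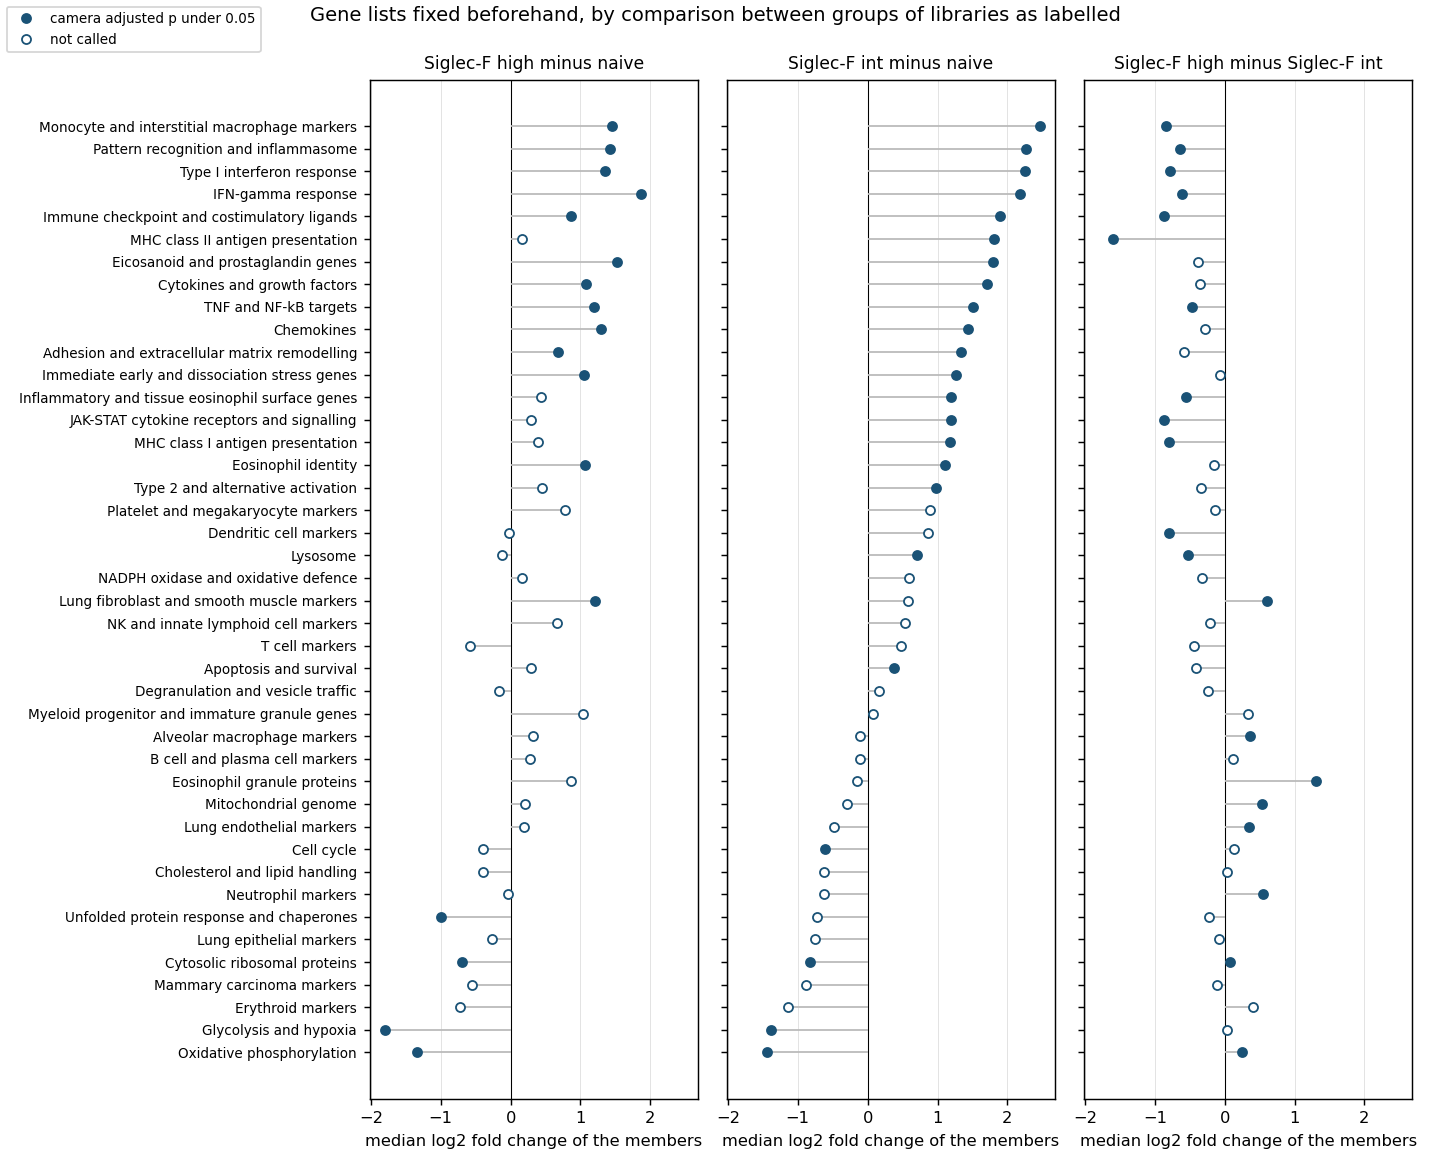
Median log2 fold change of the tested members of each gene list (horizontal axis) in the 3 comparisons between groups of libraries as labelled (n = 3 per group), where filled points have a camera adjusted p under 0.05 and open points do not. Oxidative phosphorylation had medians of -1.34 and -1.44 against the libraries labelled naive and 0.24 between high and int, where MHC class II had -1.60.

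The third comparison asked how the cells with high and intermediate Siglec-F differ. As a list, genes of MHC class II antigen presentation were lower in the libraries labelled Siglec-F high than in those labelled Siglec-F int (median of 15 members -1.60, camera adjusted p = 1.11e-06, adjusted p = 0.367 with an estimated correlation). H2-Eb1, a class II chain (ENSMUSG00000060586.10; chromosome 17, 34305867 to 34316674), stood at 8879 ± 8775 and 32308 ± 26982 in the high and int groups (-1.99 ± 0.73), H2-Aa at 9559.9 ± 6375 and 27232 ± 22912 (-1.47 ± 0.65) and H2-Ab1 (chromosome 17, 34257689 to 34269419) at 9208 ± 6670.2 and 23625 ± 19941 (-1.34 ± 0.69), none of them called (limma adjusted p = 0.797 for each). H2-Aa and H2-Ab1 were at -0.82 and -0.70 without int library 2 and at -0.85 and -0.72 without high library 3. Markers of fibroblasts and smooth muscle were higher as a list (median 0.61 over 14 members, camera adjusted p = 1.31e-05, adjusted p = 0.367 with an estimated correlation), with the collagen gene Col3a1 at 16878 ± 3234 and 10759 ± 4956. So were markers of alveolar macrophages (median 0.37 over 15 members, camera adjusted p = 0.00151, adjusted p = 0.367 with an estimated correlation) and nuclear genes of oxidative phosphorylation (median 0.24 over 38 members, camera adjusted p = 0.000107, adjusted p = 0.367 with an estimated correlation). The list of cytokine receptors and JAK-STAT signalling was lower (median -0.87 over 27 members, camera adjusted p = 1.31e-05, adjusted p = 0.367 with an estimated correlation). These 5 lists held no member called over all genes, and when adjusted over the list alone the alveolar macrophage list had 1 higher member and the other 4 had 0. All 5 were called in each alternative run with the preset correlation, with a highest adjusted p of 0.0213, for oxidative phosphorylation. Their medians depended on single libraries. Without int library 2 they were -1.06 for MHC class II, 0.31 for fibroblasts, 0.57 for alveolar macrophages and 0.44 for oxidative phosphorylation, and the last was 0.15 without int library 3. The typical fibroblast and smooth muscle marker stood at 1919, 1740 and 1664 in high libraries 1, 2 and 3 and at 1427, 737 and 1263 in int libraries 1, 2 and 3. The median of alveolar macrophage markers was 0.62 and 0.56 without high libraries 2 and 3, and that of JAK-STAT genes -0.33 without high library 1.

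Markers of monocytes and interstitial macrophages moved with the MHC class II list (median -0.85 over 16 members, camera adjusted p = 0.000174, adjusted p = 0.367 with an estimated correlation), with the lipoprotein gene Apoe (chromosome 7, 19696109 to 19699188) at 11898 ± 4958 and 28416 ± 17577 in the libraries labelled Siglec-F high and int. Dendritic cell markers, which include H2-Ab1, also moved with it (median -0.80 over 10 members, camera adjusted p = 0.0221, adjusted p = 0.367 with an estimated correlation), with Ccr7, a chemokine receptor of migrating dendritic cells, at 37.8 ± 14.1 and 128 ± 95.5. That list was not called without int library 2 (0.292), high library 2 (0.103) or high library 3 (0.151) or after removal of the GC and length trend (0.0615), with a range of 0.00332 to 0.292. Siglec-F int library 2 held the highest class II values, with H2-Ab1 at 46651 against 12091 and 12132 in int libraries 1 and 3. Without int library 2 the call of the monocyte and macrophage list was lost (adjusted p = 0.175, range over its alternatives 6.10e-07 to 0.182). So were those of type I interferon response (0.304, range 3.06e-07 to 0.304), pattern recognition (0.175, range 1.34e-06 to 0.175), MHC class I (0.112, range 3.20e-06 to 0.184) and lysosome genes (0.237, range 1.57e-07 to 0.468), whose medians were -0.79, -0.64, -0.80 and -0.52 with all libraries. With an estimated correlation none of these 4 was called either (adjusted p = 0.367 for each). Without int library 2 these medians were -0.36, -0.33, -0.38 and -0.15, that of the monocyte and macrophage list -0.32 and that of dendritic cell markers -0.39. Without high library 1 they were -0.41 for MHC class I and -0.47 for dendritic cell markers, and without int library 1 -0.83 for lysosome genes. The lower calls of TNF and NF-kB targets (median -0.47) and of checkpoint and costimulatory ligands (median -0.86) were lost without int library 2 (0.179 and 0.175) or high library 2 (0.0905 and 0.0551), with ranges of 2.77e-06 to 0.179 and 1.45e-05 to 0.175, and with an estimated correlation (0.367 for both). That of IFN-gamma response genes (median -0.62) was lost without int library 2 (0.238), high library 2 (0.0857) or high library 3 (0.105), with a range of 9.86e-05 to 0.238, and with an estimated correlation (0.367). Without int library 2 the medians were -0.31 for TNF targets, -0.53 for checkpoint ligands and -0.30 for IFN-gamma response, and without high library 1 -0.52 and -0.40 for the latter pair. The eosinophil granule list was called higher (median 1.31 over 5 members, camera adjusted p = 0.0105, adjusted p = 0.367 with an estimated correlation). That call was lost without high library 3 (0.264, median 0.79), int library 1 (0.0886) or after removal of the GC and length trend (0.0949), with a range of 0.00137 to 0.264. Ear1, Ear2 and Ear6 made up the rise, with means of 140, 409 and 97.5 in the high group and 46.3, 170 and 31.0 in the int group. Ear1 and Ear2 are also in the alveolar macrophage list. Prg2 was at 0.005, or -2.25 without high library 3, and Rnase2a, near the floor, averaged 7.19 and 5.55. The mitochondrial genome was called higher (median 0.53, camera adjusted p = 0.000107, adjusted p = 0.367 with an estimated correlation). Its median was 0.83 without high library 2, and it was not called without high library 1 (0.158, median 0.08) or after removal of the GC and length trend (0.375), with a range of 1.34e-05 to 0.375.

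**Figure D4:**
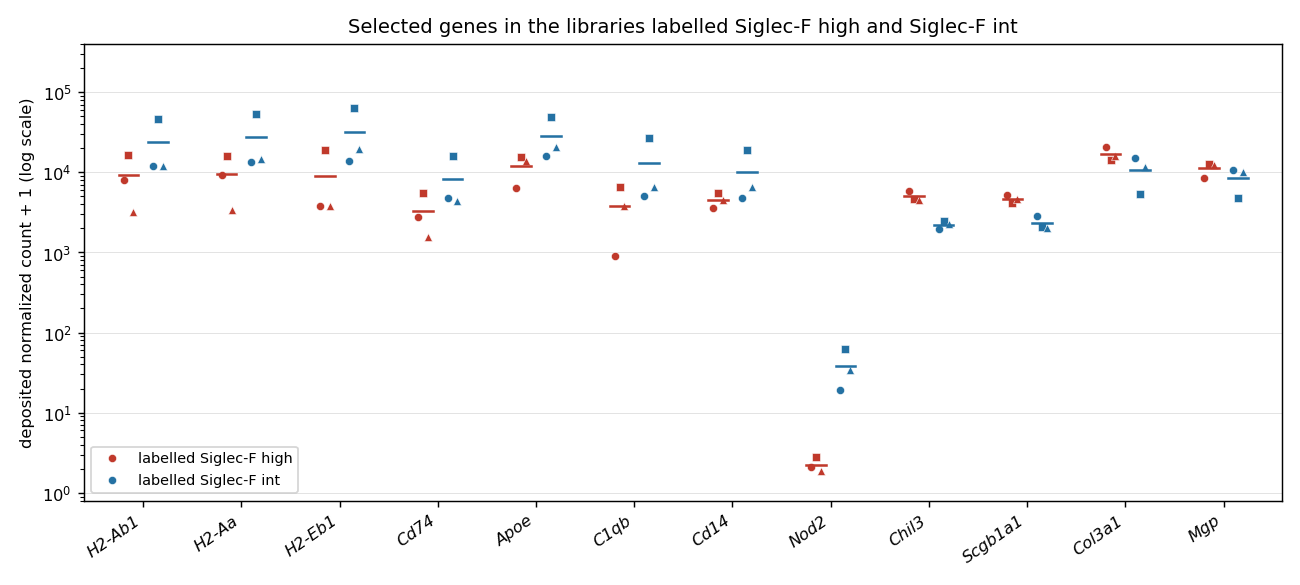
Deposited normalized counts + 1 (log axis) of selected genes in the libraries labelled Siglec-F high and Siglec-F int, where each point is a library, its shape the replicate number and each line a group mean (n = 3). H2-Ab1 averaged 9208 and 23625 and Chil3 5025 and 2217 in the high and int groups, and limma called 0 genes.

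Between the libraries labelled Siglec-F high and int, limma called 0 of 13642 genes, with 591 at an unadjusted p under 0.05 and a smallest adjusted p of 0.797, and edgeR called 0, with 636 at an unadjusted p under 0.05. DESeq2 called 6 genes, named here after their values were seen except Chil3. Chil3, a chitinase-like protein of macrophages (chromosome 3, 106147554 to 106167564), was higher in the high group at 1.21 ± 0.28 (DESeq2 adjusted p = 0.0449). Rhd, Nrxn3 and Nek5 were also called higher (adjusted p = 0.0449, 0.0126 and 0.0398), with 50, 112 and 90 reads in the high group and 2, 0 and 1 in the int group. In Siglec-F high libraries 1, 2 and 3 these were 33, 2 and 15 reads of Rhd, 87, 14 and 11 of Nrxn3 and 33, 13 and 44 of Nek5. Nod2, a sensor of bacterial peptidoglycan, was lower at -4.86 ± 1.13 (adjusted p = 0.0449), with means of 1.25 ± 0.487 and 37.8 ± 22.2, and 6530402F18Rik was lower at -3.49 ± 0.79 (adjusted p = 0.0398). Scgb1a1, the club cell secretoglobin, stood at 4653 ± 589 and 2333 ± 482 (1.01 ± 0.30), a difference limma did not call. Camera called 20 of 42 lists, 8 higher and 12 lower, and none with an estimated correlation, where the smallest adjusted p was 0.367. Equal totals moved the median log2 fold change of all genes from -0.08 to -0.20 and quantile normalization to 0.03. On simulated data limma recovered 71.3% of 16-fold, 22.99% of 4-fold and 0.299% of 2-fold changes between these groups. With 3 pools per group, most 4-fold and nearly all 2-fold differences in single genes would thus be missed.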

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

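The tests on displaced names, GC content between pairs of high libraries, exchanged libraries, a minor impurity, other material, sequencing depth, the macrophage share, the macrophage list without int library 2 and the number of genes called in other splits were chosen after the result was seen. The lists named first stood out because they were called in both comparisons with the libraries labelled naive and the difference between high and int was itself tested and called. The median log2 fold change between the libraries labelled Siglec-F high and int was -0.62 for IFN-gamma response (camera adjusted p = 0.00484, or 0.367 with an estimated correlation), -0.79 for type I interferon response (0.000107, or 0.367) and -0.47 for TNF and NF-kB targets (0.00234, or 0.367). It was -0.86 for checkpoint and costimulatory ligands (0.00170, or 0.367 with an estimated correlation), -0.64 for pattern recognition (0.000135, or 0.367) and -0.85 for monocyte and interstitial macrophage markers (0.000174, or 0.367). Nuclear genes of oxidative phosphorylation had 0.24 (0.000107, or 0.367 with an estimated correlation), and ribosomal protein genes 0.072 (0.010, or 0.646). The ribosomal median was -0.06 with equal totals, -0.03 without high library 2 and -0.05 without int library 3. It was 0.25 without high library 1 and 0.30 without int library 2, so its sign was not settled. Against naive, the checkpoint call in the high group was lost without naive library 1 (0.112), without high library 2 (0.0755) and with a mean of at least 20 (0.0706), over a range of 0.00625 to 0.112, and with an estimated correlation (0.584). The ribosomal calls against naive were lost after removal of the GC and length trend, in the high group (0.946, range 1.99e-06 to 0.946) and in the int group (0.0621, range 6.93e-14 to 0.0621), and with an estimated correlation (0.687 and 0.338). With an estimated correlation none of the 8 was thus called between high and int. Of these 8, oxidative phosphorylation alone was called whichever library was left out. Without Siglec-F int library 2 the adjusted p was 0.238 for IFN-gamma response, 0.304 for type I interferon, 0.179 for TNF targets, 0.175 for checkpoint ligands, 0.175 for pattern recognition and 0.175 for monocyte and macrophage markers. The medians were then -0.30, -0.36, -0.31, -0.53, -0.33 and -0.32, and that of oxidative phosphorylation 0.44. Without Siglec-F high library 2 it was 0.0857 for IFN-gamma response, 0.0905 for TNF targets and 0.0551 for checkpoint ligands, and without high library 3 0.105 for IFN-gamma response. For ribosomal proteins it was 0.351, 0.172, 0.190 and 0.489 without high libraries 2 and 3 and int libraries 1 and 3. Over the alternatives the adjusted p ran from 9.86e-05 to 0.238 for IFN-gamma response, 3.06e-07 to 0.304 for type I interferon, 2.77e-06 to 0.179 for TNF targets, 1.45e-05 to 0.175 for checkpoint ligands, 1.34e-06 to 0.175 for pattern recognition, 6.10e-07 to 0.182 for monocyte and macrophage markers, 1.83e-21 to 0.0213 for oxidative phosphorylation and 6.75e-37 to 0.489 for ribosomal proteins.

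Siglecf, Ccr3, Il5ra and Epx were near the floor in all 9 libraries, while pigment cell transcripts were abundant in those labelled naive. Displaced gene names would scatter known abundant genes, but 11 protein genes of the mitochondrial genome were among the 200 highest in the libraries labelled naive. With only a minor impurity, eosinophil transcripts should not lie far below those of the impurity, but 6 of them came to 0.0359% of the pigment markers at most. Sums over such different genes do not measure shares of cells. An exchange of whole groups cannot be told apart from labels in place, since the lowest median of the pigment markers in a naive library, 28.2 times the highest elsewhere, would be the same. Libraries or a table of other material under these labels could not be excluded and may be the source. Pigment markers took at least 1.52% of the total in each library labelled naive, with Dct at 22839 and Pmel at 15399. A sort on surface Siglec-F should remove such cells. Saline and tumour-injected mice were compared only as labelled, so an effect of the injection on these transcripts cannot be told apart from other material.

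Siglec-F high library 1 stood apart from Siglec-F high libraries 2 and 3, with a median absolute log2 deviation of 1.08 from them. Too few reads would need a shallow library, but it held 0.960 times the reads of the shallower of the others. The deviation went with GC content across genes (Spearman rho -0.496), as did its differences from library 2 (-0.532) and library 3 (-0.429), but the difference between libraries 2 and 3 went with it too (0.376), so GC bias cannot be told apart from other causes. Transcript length (rho 0.181) was related too weakly to decide, and mitochondrial genes took 31.1% (95% Wilson interval 31.0 to 31.1) of its reads, 13.9% (95% Wilson interval 13.9 to 13.9) in library 2 and 19.8% (95% Wilson interval 19.7 to 19.8) in library 3. A biological difference between the pools was not tested.

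MHC class II and macrophage lists were lower in the libraries labelled Siglec-F high than in those labelled Siglec-F int. At the preset correlation, camera still called the MHC class II list without Siglec-F int library 2 (adjusted p = 0.000954). It did so too after removal of the GC and length trend (adjusted p = 4.02e-07). The range over the alternatives with that correlation was 5.13e-12 to 0.00134. With an estimated correlation the list was not called (adjusted p = 0.367), so these tests exclude neither that library nor GC bias. H2-Ab1 was at -1.34, or -0.70 without int library 2 and -0.72 without high library 3. The macrophage list was not called without int library 2 (adjusted p = 0.175, range 6.10e-07 to 0.182), which leaves that library open for it, and the medians of the MHC class II and macrophage lists were then -1.06 and -0.32, with C1qb at 5116, 27139 and 6639 in int libraries 1, 2 and 3. A lower share of monocytes and interstitial macrophages among the cells collected as Siglec-F high could be a candidate source. Their list had a median of -0.85, with Apoe at 11898 and 28416 in the high and int groups. Dendritic cell markers went the same way (-0.80). Alveolar macrophage markers went the other way (0.37), but they mark another kind of macrophage and include Siglecf, the gene of the sort marker. Their direction thus does not bear on that candidate. A lower share of monocytes and interstitial macrophages cannot be told apart from a lower share of dendritic cells or an untested difference within the cells. Bulk libraries hold all of these cells, and a sort that removes cells with markers of either type would separate these possibilities.

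Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. Between high and naive the real groups gave 4266 genes and 17 lists, and the highest other split 0 genes and 19 lists, with 1 and 2 of the 10 splits giving as many. Between int and naive the real groups gave 3036 genes and 23 lists and the highest other split 0 and 25, with 1 and 4 splits giving as many. Between high and int the real groups gave 0 genes (591 at an unadjusted p under 0.05) and 20 lists and the highest other split 0 and 20, with 10 and 2 splits giving as many.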

How the results depend on the processing

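The alternatives without a pair of libraries, without the GC and length trend and without the mitochondrial genes were chosen after seeing the data. Among named genes, 89 of 145 calls between high and naive and 96 of 134 between int and naive were made under every alternative, as were 13 of 17, 17 of 23 and 5 of 20 list calls in the 3 comparisons, the estimated correlation set aside. With only the 2 groups compared, 2509 genes were called between high and naive (1207 higher, 1302 lower) and 4808 between int and naive (2669 lower). edgeR called 1378 lower genes between high and naive, and equal totals gave 898 lower between int and naive. With both Siglec-F high library 1 and Siglec-F int library 2 left out, 4623 genes were called between int and naive (2567 lower). DESeq2 called 6 genes between high and int (4 higher, 2 lower). Leaving out each library in turn, the calls ran from 2770 to 5101 between high and naive (lower genes 1336 to 2930), from 1401 to 5167 between int and naive (higher 751 to 2407, lower 650 to 2760), and from 1275 to 3594 in their overlap. Where a group was left with fewer libraries, they were assumed to vary like the other groups. After removal of the GC and length trend 45 named gene calls were lost between high and naive, against 26 at most under any other alternative, and 18 between int and naive, against 33 at most. Between high and naive, Hsp90b1 and Ramp2 also reversed, to -0.031 and 0.41. The cause was not tested. With the replicate number as a replicate block, 4317, 3091 and 0 genes were called in the 3 comparisons. The numbers were not taken as pairs, because the labels do not say that equal numbers mark a shared pool of mice. Correlations of high and int libraries were 0.123, 0.141 and 0.0718 for equal numbers. For unequal numbers they ran from -0.157 to -0.0105. They were weak, but pools or batches shared by equal numbers are thus not excluded, and the main fit took no account of them. The fewest reads, 2205949, were in naive library 2 and limit what low genes can show.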

Other observations

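Further gene groups differed from the libraries labelled naive. Of 19 eicosanoid and prostaglandin genes 6 rose in the libraries labelled Siglec-F high, or 8 when adjusted over the list alone (camera adjusted p = 0.00758, adjusted p = 0.287 with an estimated correlation). In those labelled Siglec-F int 7 rose and 1 fell, or 10 and 1 when adjusted over the list alone (camera adjusted p = 0.000827, adjusted p = 0.114 with an estimated correlation). They included Pla2g7, a lipase of platelet-activating factor, at 2.59 ± 0.29 and 2.68 ± 0.29, and Pla2g4a, which releases arachidonic acid, at 4.98 ± 0.79 and 4.35 ± 0.79. Of 27 genes of adhesion and matrix remodelling 8 and 10 rose, or 8 and 11 when adjusted over the list alone (camera adjusted p = 0.000473 and 7.16e-07, adjusted p = 0.322 and 0.114 with an estimated correlation). Thbs1, a matricellular glycoprotein, was at 2.68 ± 0.38 and 2.72 ± 0.38, and Tgfbi, a matrix protein induced by TGF-beta, at 2.48 ± 0.41 and 3.21 ± 0.41. Asns and Chac1, targets of the amino acid stress response, were at -2.58 ± 0.28 and -4.08 ± 0.57 in the libraries labelled Siglec-F high. The unfolded protein response and chaperone list, which holds both, had medians of -0.99 and -0.73 in those labelled Siglec-F high and int. In the int group it was called only under 10 alternatives, and an estimated correlation gave no call in either group. Gata3, a transcription factor of type 2 lymphocytes and of epithelia, was at 5.88 ± 0.69 and 5.65 ± 0.69 in those labelled Siglec-F high and int.

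The mesenchymal and matrix list, chosen after the values were seen, took 0.340% (95% Wilson interval 0.333 to 0.348) to 0.458% (0.453 to 0.464) of the reads in the libraries labelled naive. In those labelled Siglec-F high it took 1.39% (1.38 to 1.41) to 1.48% (1.47 to 1.49). In the int group it took 1.45% (1.45 to 1.46), 0.640% (0.635 to 0.644) and 1.38% (1.38 to 1.39), with the lowest share in library 2. The log2 fold changes of all genes correlated with GC content across genes, which are not independent replicates, with a Spearman rho of -0.484 between high and naive, -0.367 between int and naive and -0.377 between high and int.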
